A study of Mus musculus with 6 samples.

How the data were processed

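Bulk RNA-seq was available for 6 libraries of mouse bone marrow. Per the labels, 2 libraries came from marrow cultures in control medium (replicates 1 and 2) and 4 from cultures in conditioned medium, which is medium in which tumour cells had been grown. The 4 conditioned media came from clear cell renal cell carcinoma (ccRCC) cell lines named VpR83, VpR99, VpR126 and VpR2020, with 1 library per line. The lines therefore served as the replicates of conditioned medium, and no line could be tested against another. Nothing in the labels says whether the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, part of which may be technical. The sample labels name control medium, while the series' design text names freshly isolated marrow as the comparator. The groups follow the sample labels. Culture times, animals and batches are not given in the sources used here.

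Libraries were made with a stranded Illumina TruSeq kit from total RNA, per the labels' protocols. Trimmomatic 0.38, STAR 2.5.2b and the mouse genome build GRCm38 are named in the submitters' processing notes. The counting tool, its strand setting and its annotation release are not given in the sources used here. The deposited values are raw read counts per Ensembl mouse gene, made by the authors and not normalized, for 45706 gene identifiers. All 6 columns were mapped to samples by name. The columns of the controls are headed as bone marrow with a replicate number and name no medium. The headers of VpR83, VpR99 and VpR126 carry the further tags Ctrl, T1 and LT2, in this order, which the labels do not explain. Of the identifiers, 45143 matched GENCODE M21, an annotation of GRCm38, which supplied symbols and coordinates. The unmatched identifiers held 0.0538% to 0.0828% of the counts of a library. Reads of near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Fdps and its processed pseudogenes) may be split or lost by the counting. Whether this also touches the related but less similar chemokine genes Ccl2, Ccl7 and Ccl12 was not checked. Overlapping antisense genes cannot be separated without the strand setting. Values of single genes of these kinds are uncertain.

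Total counts were 27448621 and 18629708 in control replicates 1 and 2, and 28055913 (VpR83), 129120559 (VpR99), 25714176 (VpR126) and 19412158 (VpR2020) in the conditioned libraries. A count of 0 allows up to 3 counts, which corresponds to 0.0232 CPM in the deepest library and 0.161 CPM in the shallowest. These floors are on library totals. Floors and all counting intervals cover counting error only. The chi-square per degree of freedom of the control pair was 31.2, the lowest of the library pairs, so no library repeated another within sampling noise.

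The counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its defaults, which kept 15141, and libraries were scaled by TMM. Conditioned medium was compared with control medium by edgeR's robust quasi-likelihood test with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. CPM values are TMM-scaled and given as mean ± SD (n = 2 control and n = 4 conditioned libraries), and log2 fold changes are given ± SE. This SE is the absolute log2 fold change divided by the square root of edgeR's F statistic, and is not an SE fitted by the model. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the whole group. Where it had 1 to 3 counts, the ratio of pooled CPM is given with its exact 95% Poisson interval.

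The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where stated. The 26 gene lists, drawn from textbook knowledge, were T cell suppression, inflammatory cytokines and chemokines, alternative macrophage activation, interferon-stimulated genes, MHC class II presentation, glycolysis and hypoxia response, cholesterol synthesis, lysosome, cell cycle, endoplasmic reticulum stress and immediate early stress, and markers of neutrophil primary granules, late neutrophils, monocytes, macrophages, osteoclasts, dendritic cells, B cells, T and NK cells, erythroid cells, megakaryocytes and platelets, mast cells and basophils, eosinophils, haematopoietic stem and progenitor cells, stromal and endothelial cells, and epithelial cells as a sign of carried-over tumour cells. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), two-sided, adjusted over the 26 lists. The gene numbers given for a list are of its tested members, without those filtered out for low counts. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance one way and does not compare the list with other genes.

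Named genes were the 12 largest rises and 12 largest falls among called genes with a mean of at least 4 log2 CPM and all 4 conditioned libraries on one side of both controls (without predicted genes, pseudogenes and receptor segments), 20 genes fixed whatever their result, up to 4 called members of each list with the smallest adjusted p, and the members of counts of 5 or fewer. The first 3 parts gave 123 genes. Other genes are said to be chosen after their values were seen. Some genes under this rule are not reported here. Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma voom, no filter and a stricter filter, other thresholds, each library left out in turn, and, for lists, the estimated correlation and members of 1 list only. Thinning of VpR99 to the median total of the others was added after the totals were seen. The steps were tested on simulated counts of 14733 genes of this comparison, 200 of them changed. There edgeR recovered 65% of 4-fold and 2% of 2-fold changes with 3 false calls among 70, voom 63% and 2% with 2 among 67, and DESeq2 84% and 30% with 63 among 177. Far fewer genes changed there than the 6393 called in the real data, so these rates need not hold for the real comparison.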

Results

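RNA-seq libraries were compared between mouse bone marrow in control medium (2 libraries) and in medium conditioned by ccRCC cells of the lines VpR83, VpR99, VpR126 and VpR2020 (4 libraries, 1 per line). The series concerns the crosstalk of tumour cells with myeloid and T cells in a mouse ccRCC model resistant to checkpoint therapy, and the comparison asks how marrow cells differ after exposure to tumour cell medium. Total counts ranged from 18629708 to 28055913 in 5 libraries and reached 129120559 in VpR99. The most abundant transcript was S100a9, which encodes a calcium-binding protein of neutrophils, in both controls (3.35% and 3.08% of counts), and Lyz2, the lysozyme of myeloid cells, in all 4 conditioned libraries (1.28% to 3.03%). Because the design text of the series names freshly isolated marrow and the sample labels name control medium, and the column headers of the controls name no medium, time in culture may differ between the groups together with the medium.

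Macrophage, lysosomal and cholesterol synthesis genes were higher in conditioned medium, and genes of erythroid, lymphoid and granulocytic cells were lower. Of 15141 genes tested, 3410 were called higher and 2983 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the called genes, the fitted difference exceeded 2-fold for 2417 higher and 2216 lower genes, and 8-fold for 594 and 811. No test against these folds was run. In 6387 of the 6393 called genes, all 4 conditioned libraries lay on one side of both controls. This held for 65.3% of all tested genes, against 13.3% by chance. Higher genes made up 53.3% of the calls, but 40.0% under upper-quartile scaling and 38.6% with library totals only, where the median log2 fold change of all genes was -0.22 and -0.26 in place of -0.01. Without control replicate 1 or 2, 2201 and 2290 genes were called, the lone control then being assumed to vary like the conditioned libraries.

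The 12 largest rises under the naming rule had log2 fold changes of 8.87 to 13.55. Gpnmb, a transmembrane glycoprotein gene of phagocytes (chromosome 6, 49036546 to 49070929, GRCm38), rose from 0.927 ± 0.0851 to 11124 ± 3818 CPM, a log2 fold change of 13.55 ± 0.66 (edgeR adjusted p = 0.00016). Arg1, which encodes the arginine-degrading enzyme arginase 1 (chromosome 10, 24915221 to 24927484), rose from 0.107 ± 0.0846 to 806 ± 598 CPM (12.73 ± 1.62, adjusted p = 0.0022), with 137 CPM under VpR126 medium and 1538 CPM under VpR99 medium. C3ar1, the receptor gene of complement fragment C3a, reached 845 ± 55.6 CPM from 1.36 ± 0.00255 (9.27 ± 0.24). The scavenger receptor gene Stab1, the endocytic adaptor gene Dab2, the membrane protein gene Pmp22 and the Fc receptor-like gene Fcrls rose by 10.11 ± 0.89, 9.77 ± 0.51, 8.87 ± 0.57 and 10.45 ± 1.54. Spint1, a protease inhibitor gene, had 2 counts in the controls together and was 2958-fold higher in conditioned medium (counting interval 819 to 24422). Both counts lay in control replicate 1. Without that library Spint1 was at least 818-fold higher, without control replicate 2 1730.4-fold (counting interval 479 to 14289) and without VpR99 1638-fold (counting interval 453 to 13523). Mmp12, the macrophage elastase gene, the acute-phase gene Saa3 and the chemokine genes Ccl7 and Ccl12 rose by 13.09 ± 2.21, 11.38 ± 2.51, 9.60 ± 1.63 and 9.44 ± 1.91. These folds rest on few control counts. Control replicate 2 had 0 counts of Mmp12 and Ccl12, so their values without control replicate 1 are fitted and are not lower bounds. Without control replicate 1 the fitted log2 fold changes were 18.41 for Mmp12 and 14.20 for Ccl12. Those of Ccl7, Saa3 and Arg1 were then 12.18, 10.36 and 13.97. The fold of Saa3 was 13.58 without control replicate 2 and 9.96 without VpR126. Those of Mmp12, Ccl7 and Ccl12 were 12.31, 8.88 and 8.68 without control replicate 2, and 12.45, 8.46 and 7.98 without VpR99. Significance was lost in the case of Saa3 without control replicate 1 or control replicate 2 (adjusted p = 0.10 and 0.082, range 6.9e-11 to 0.13) or by voom or without a low-count filter (0.13 and 0.075) and of Ccl12 without control replicate 1 or control replicate 2 (adjusted p = 0.069 and 0.077, range 1.5e-08 to 0.088) or by voom or without a low-count filter (0.088 and 0.059). No call was made of Mmp12 without control replicate 2 (adjusted p = 0.054, range 2.7e-14 to 0.061) or by voom (0.061) and of Ccl7 without control replicate 2 (adjusted p = 0.052, range 1.7e-20 to 0.052). Ranges are those over the alternatives of a result.

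Macrophage markers rose together. Of 16 tested, 14 were called higher, 1 lower and 1 was not called (14 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 4.82 (camera adjusted p = 1.3e-07, and adjusted p = 0.52 with an estimated correlation). Mrc1, the mannose receptor gene (chromosome 2, 14229392 to 14332057), rose from 38.5 ± 3.77 to 1324 ± 129.5 CPM (5.10 ± 0.23, edgeR adjusted p = 0.00013). Adgre1, the gene of the macrophage antigen F4/80, rose from 39.2 ± 4.75 to 988 ± 524 CPM, and Csf1r, the receptor gene of macrophage growth factor CSF1, from 168 ± 2.35 to 2554 ± 1611 CPM. The lysosomal glycoprotein gene Cd68 and the lipid receptor gene Trem2 rose by 3.84 ± 0.32 and 5.27 ± 0.47. Against the list, the adhesion molecule gene Vcam1 fell by 2.96, and Cd14, a coreceptor for bacterial lipopolysaccharide, was not called (2.02, adjusted p = 0.13). The threshold was missed in the case of Csf1r without control replicate 1 or control replicate 2 (adjusted p = 0.067 and 0.064, range 1.2e-10 to 0.067). Without control replicate 1 or 2, 11 and 10 markers were called higher, and Vcam1 was not called, nor without a low-count filter. Without VpR126 the log2 fold change of Vcam1 was -3.83.

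Every tested lysosomal and cholesterol synthesis gene rose. The 16 lysosome genes and the 16 cholesterol genes were all called higher, also adjusted over the list alone. The lysosome list had a median log2 fold change of 2.66 (camera adjusted p = 5.5e-09, and adjusted p = 0.34 with an estimated correlation), and the cholesterol list one of 2.55 (camera adjusted p = 1.1e-08, and adjusted p = 0.52 with an estimated correlation). The cathepsin genes Ctsb and Ctsz, which encode lysosomal proteases, rose by 4.64 ± 0.35 and 2.63 ± 0.21, the lysosomal acid lipase gene Lipa by 4.22 ± 0.36 and the membrane protein gene Lamp2 by 2.28 ± 0.20. Hmgcs1 and Idi1, enzyme genes of the mevalonate pathway, rose by 2.80 ± 0.29 and 2.51 ± 0.24. The sterol transfer gene Stard4 rose from 26 ± 3.22 to 129.8 ± 22.8 CPM (2.32 ± 0.22, edgeR adjusted p = 0.0010). The lysosome list's mean over control lay between 2.87 and 3.27 log2 units in the 4 lines, and the cholesterol list's between 2.15 and 2.87. The counts of genes called were 13 (lysosome) and 15 (cholesterol) without control replicate 1 and, without replicate 2, 15 and 15.

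**Figure D1:**
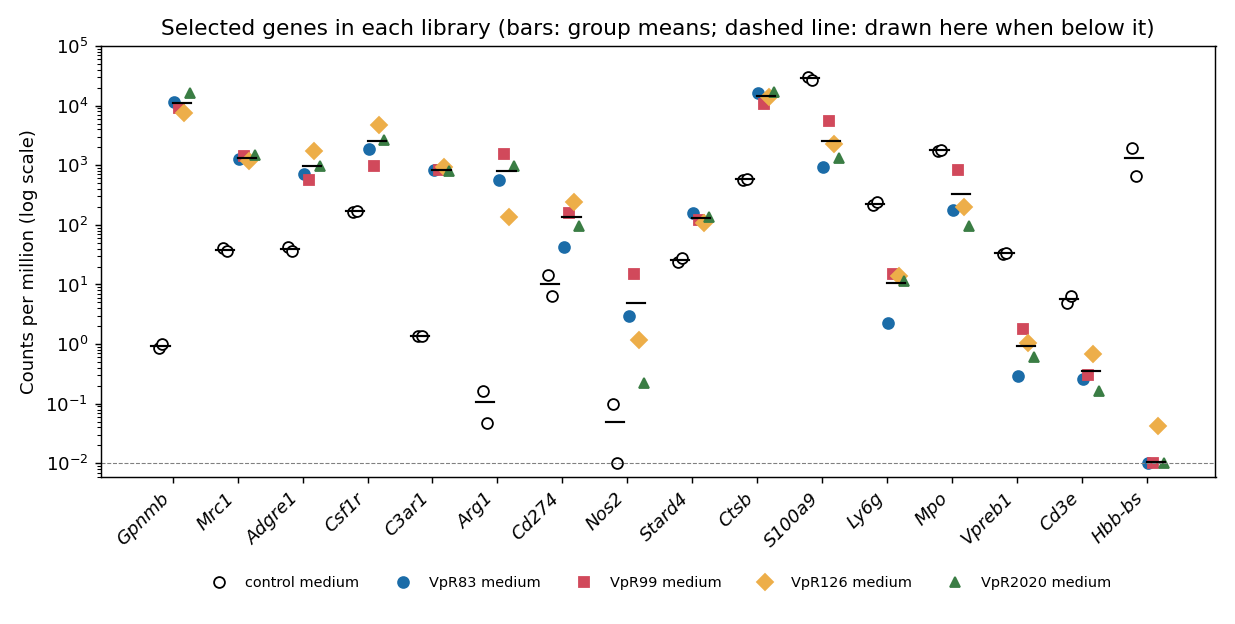
CPM on a log axis of selected genes in each library, with open circles for the 2 control libraries, filled symbols for the 4 conditioned libraries and bars for group means; values below the dashed line are drawn on it. Mrc1 lies between 1172 and 1458 CPM in the 4 conditioned libraries, above 41.2 and 35.9 CPM in the controls, while Hbb-bs falls from 1981 and 653 CPM to at most 0.0422 CPM.

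Genes whose products restrain T cells changed in part. Of 15 tested, 6 rose, 1 fell and 8 were not called (7 higher and 1 lower adjusted over the list alone), and the list was not called as a set (median 0.76, camera adjusted p = 0.11). Besides Arg1, Cd274, the PD-L1 gene (chromosome 19, 29367455 to 29388095), rose from 10.3 ± 5.6 to 133 ± 83.9 CPM (3.69 ± 0.81, edgeR adjusted p = 0.013). The ectoenzyme gene Entpd1 rose by 1.88 ± 0.43, the checkpoint receptor gene Havcr2 by 4.36 ± 1.02 and the angiogenic factor gene Vegfa by 1.59 ± 0.40. Ptgs2, the cyclooxygenase 2 gene, fell by 2.98, with 110.3 and 12.5 CPM in the 2 controls. Nos2, the inducible nitric oxide synthase gene, had 3 counts in the controls together and from 0.221 to 14.9 CPM in the conditioned libraries (adjusted p = 0.057). It was called without VpR2020 or by DESeq2 (adjusted p = 0.035 and 0.00022, range 0.00022 to 0.23). Il10 had 0.361 ± 0.244 and 3.21 ± 4.69 CPM (adjusted p = 0.16), and was called higher by DESeq2 (adjusted p = 0.031, range 0.031 to 0.43). The test no longer passed in the case of Cd274 without control replicate 1 or control replicate 2 (adjusted p = 0.061 and 0.096, range 1.6e-07 to 0.096) or without a low-count filter (0.052) and of Entpd1 without control replicate 1 or control replicate 2 (adjusted p = 0.11 and 0.086, range 0.00010 to 0.11). Significance was lost in the case of Havcr2 without control replicate 1 or control replicate 2 (adjusted p = 0.10 and 0.11, range 2.3e-07 to 0.11) or by voom or without a low-count filter (0.091 and 0.063) and of Vegfa without control replicate 1 or control replicate 2 (adjusted p = 0.072 and 0.14, range 0.00067 to 0.14). Without either control 1 member was called higher, and Ptgs2 was not called without control replicate 1, VpR83 or VpR2020, by voom or without a low-count filter. The log2 fold change of Ptgs2 was -0.69 without control replicate 1 and -3.80 without replicate 2, and that of Cd274 4.38 without replicate 1. Without VpR83 or without a low-count filter the list was called as a set (camera adjusted p = 0.043 and 0.031, range 0.031 to 0.52).

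Inflammatory and alternative activation genes moved both ways. Of 16 inflammatory cytokine and chemokine genes 6 rose and 2 fell (7 higher and 3 lower adjusted over the list alone, median 1.09, camera adjusted p = 0.051). The chemokine gene Ccl9 rose by 2.46 and the interleukin gene Il1a by 3.85. The cytokine genes Il1b and Osm changed by -2.58 and -2.40, but Il1b had 394 CPM in control replicate 1 and 83.6 in replicate 2, and without replicate 1 neither was called (-1.06, adjusted p = 0.21, range 0.00023 to 0.21, and -1.71, adjusted p = 0.073, range 8.8e-06 to 0.073), nor Il1b without a low-count filter (0.077). Without replicate 2, Il1b changed by -3.28. Il6 had 16.8 and 1.36 CPM in the controls and 0.6 ± 0.897 in conditioned medium (adjusted p = 0.057). It was called lower without VpR126, under upper-quartile scaling, with library totals only, by DESeq2 and by voom (adjusted p = 0.011, 0.046, 0.042, 0.0064 and 0.044, range 0.0064 to 0.61). Of 12 tested alternative activation genes 5 rose (Mrc1, Arg1, Msr1, Ccl22 and Ccl24) and 1 fell (6 higher and 1 lower adjusted over the list alone, median 1.93, camera adjusted p = 0.035, and adjusted p = 0.52 with an estimated correlation). Retnla and Ccl17 of that list had too few counts to test (7 and 52 over all libraries). The scavenger receptor gene Msr1 rose by 5.19 ± 0.52, and the chitinase-like gene Chil3 fell from 3243 ± 455 to 518 ± 267 CPM. No call was made of Il1a without control replicate 1 or control replicate 2 (adjusted p = 0.068 and 0.059, range 1.1e-08 to 0.068) and of Chil3 without control replicate 1 or control replicate 2 (adjusted p = 0.062 and 0.051, range 6.1e-06 to 0.062). Of the inflammatory genes, 4 were called higher and 0 lower without control replicate 1, 1 and 2 without replicate 2, and 6 and 4 without VpR126. Without control replicate 2, 3 alternative activation genes were called higher. The inflammatory list was called higher without control replicate 1, VpR83 or VpR2020 (camera adjusted p = 0.0033, 0.035 and 0.032, range 0.0033 to 0.69), with a median of 2.75 without that control. The same held under RLE, upper-quartile and library-total scaling, without a low-count filter and after thinning VpR99 (0.043, 0.016, 0.014, 0.0060 and 0.045). The alternative activation list was not called without VpR126 (adjusted p = 0.098, range 0.0068 to 0.52).

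Erythroid transcripts were almost absent under conditioned medium. All 14 erythroid genes fell, also adjusted over the list alone, with a median log2 fold change of -13.72, or -12.46 with the 4 members at 0 counts set to their bound (camera adjusted p = 7.4e-13, and adjusted p = 0.34 with an estimated correlation). Hbb-bs, an adult β-globin gene (chromosome 7, 103826534 to 103828096), had 1317 ± 939 CPM in control medium and 1 count in the conditioned libraries together, and was 275117-fold lower (counting interval 49378 to 10866500.0). Hba-a2, Hbb-bt, Cldn13 and Btnl10 were 63977-fold, 47437-fold, 15383-fold and 11237-fold lower, with counting intervals of 11483 to 2526950.0, 13132 to 391700.0, 2761 to 607582 and 2017 to 443831. Slc4a1, the band 3 anion exchanger gene, and Car1, a carbonic anhydrase gene, had 0 counts in every conditioned library and were at least 27612-fold and 19904-fold lower. The same held for Rhag, Kel, Slc38a5 and Trim10, at least 5046-fold, 3851-fold, 3355-fold and 3390.4-fold lower. The controls had 565 and 241 CPM of Slc4a1, which was at least 15450.2-fold lower without replicate 1. VpR99 held 64.1% of the pooled conditioned depth. Without it, the bounds of Slc4a1, Car1, Rhag, Kel, Slc38a5 and Trim10 were 9911, 7144, 1811, 1382, 1204 and 1217, and Cldn13 and Btnl10, then at 0 counts, were at least 1840.5-fold and 1344-fold lower. Hbb-bs was then 98751-fold (counting interval 17724 to 3900460.0) and Hba-a2 22964-fold (counting interval 4122 to 907029) lower. Without VpR126 these 2 genes had 0 counts and were at least 80423-fold and 18702-fold lower, and Hbb-bt 83201-fold (counting interval 14933 to 3286270.0). When control replicate 1 was left out, Hbb-bs was 125633-fold (counting interval 22549 to 4962240.0), Hba-a2 28320.3-fold (counting interval 5083 to 1118590.0) and Hbb-bt 24387-fold (counting interval 6751 to 201371) lower. Single values of the globin genes are uncertain, since their copies are near-identical. Klf1, an erythroid transcription factor gene, fell by 9.59 ± 0.33, the membrane protein gene Ermap fell by 9.75 ± 0.22 and the α-globin gene Hba-a1 fell by 13.44 ± 1.27. VpR126 held 11 of the conditioned counts of Hba-a1 and VpR83 1, and its log2 fold change was -16.65 without VpR126, -12.34 without VpR99 and -12.65 without control replicate 1.

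Lymphoid markers were lower. Of 16 T and NK cell genes 14 fell, the same number adjusted over the list alone (median -4.50, camera adjusted p = 1.3e-07, and adjusted p = 0.52 with an estimated correlation), and Il7r and Cd4 were not called (1.22 and 0.45). Cd3e, a T cell receptor complex gene, fell from 5.64 ± 1.14 to 0.352 ± 0.224 CPM, and its partner Cd3d fell by 4.68 ± 0.33. The NK receptor gene Klrb1c fell, as did the transcription factor genes Eomes and Tbx21 (log2 fold changes of -5.44, -6.10 and -4.63). Of 14 B cell genes 10 fell and 4 were not called (11 lower adjusted over the list alone, median -2.59, camera adjusted p = 0.00033, and adjusted p = 0.53 with an estimated correlation). Vpreb1 and Igll1, the surrogate light chain genes of B cell precursors, changed by -5.06 ± 0.60 and -5.51 ± 0.70, and the heavy chain gene Ighm fell by 2.79 ± 0.40. Without VpR99, Vpreb1 and Igll1 changed by -5.66 and -6.56, and without VpR126 Klrb1c changed by -6.10. Without either control 3 B cell genes were called, and without a low-count filter 5.

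Neutrophil markers were lower but remained detected. Of 17 late neutrophil genes 13 fell and 4 were not called, with the same counts adjusted over the list alone (median -3.11, camera adjusted p = 6.3e-05, and adjusted p = 0.52 with an estimated correlation). The calcium-binding protein genes S100a9 and S100a8 fell from 28772 ± 2603 to 2519 ± 2083 CPM and from 19317 ± 1806 to 1870.4 ± 1696 CPM. The surface antigen gene Ly6g fell by 4.38 ± 0.64, the antimicrobial peptide gene Camp fell by 5.95 ± 0.78, Retnlg fell by 4.13 ± 0.49 and the metalloproteinase gene Mmp25 fell by 3.11 ± 0.35. Of the 9 genes in the primary granule list 4 fell (5 adjusted over the list alone, median -2.12, camera adjusted p = 0.0058, and adjusted p = 0.55 with an estimated correlation). They were Hdc (-4.12), Fcnb (-3.23), Rab44 (-2.12) and the myeloperoxidase gene Mpo (-2.44 ± 0.80, edgeR adjusted p = 0.048). Elane, Prtn3, Ctsg, Ms4a3 and Serpinb1a were not called, and Hdc also stands in the mast cell and basophil list. The threshold was missed in the case of Mpo without control replicate 1, control replicate 2, VpR83, VpR126 or VpR2020 (adjusted p = 0.15, 0.16, 0.094, 0.084 and 0.071, range 0.0018 to 0.18) or without a low-count filter (0.18). Without VpR99, where Mpo had 831 CPM, all 9 primary granule genes were called and their median was -3.28. The log2 fold changes of Mpo, S100a9 and S100a8 were then -3.48, -4.24 and -4.22, the last 2 in place of -3.51 and -3.37. Without control replicate 1 or 2, 7 and 8 late neutrophil and 2 primary granule genes were called, and without a low-count filter 2 primary granule genes. The test no longer passed in the case of S100a8 without control replicate 1 or control replicate 2 (adjusted p = 0.066 and 0.060, range 5.9e-06 to 0.066) or without a low-count filter (0.052) and of S100a9 without control replicate 1 (adjusted p = 0.053, range 5.5e-07 to 0.053). Significance was lost in the case of Rab44 without control replicate 1 or control replicate 2 (adjusted p = 0.087 and 0.084, range 0.00027 to 0.087) or without a low-count filter (0.057).

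Markers of rarer marrow cells were mostly lower. All 9 tested genes of the mast cell and basophil list fell, also adjusted over the list alone (median -3.80, camera adjusted p = 0.0013, and adjusted p = 0.53 with an estimated correlation), among them the basophil protease gene Mcpt8 by 5.20 ± 0.94. Cma1, Mcpt4 and Tpsb2 of that list had too few counts to test (17, 0 and 4 over all libraries). Kit and Gata2 also stand in the stem and progenitor list, and Hdc in the primary granule list. Of 10 eosinophil genes 7 fell, the same number adjusted over the list alone (median -2.74, camera adjusted p = 0.019, and adjusted p = 0.53 with an estimated correlation), among them the ribonuclease gene Ear2 by 4.03 ± 0.58. Of 13 stem and progenitor genes 7 fell and 2 rose (2 higher and 7 lower adjusted over the list alone, median -1.94, camera adjusted p = 0.035, and adjusted p = 0.52 with an estimated correlation). Cd34 fell by 2.32 ± 0.29 and the cytokine receptor gene Flt3 fell by 2.68 ± 0.41, while Cd48 and Procr rose by 1.17 and 2.80. Of 12 stromal and endothelial genes 9 fell and 1, the receptor gene Kdr, rose by 3.67 (1 higher and 10 lower adjusted over the list alone, median -3.98, camera adjusted p = 0.00033, and adjusted p = 0.52 with an estimated correlation), and the chemokine gene Cxcl12 fell from 22.6 ± 4.2 to 0.213 ± 0.151 CPM. Of 7 epithelial genes, markers of carried-over tumour cells, 4 (Krt18, Krt7 and Pax8 among them) fell and 0 rose, with the same counts adjusted over the list alone (median -2.62, camera adjusted p = 0.025, and adjusted p = 0.52 with an estimated correlation). Without control replicate 1 or 2, 3 and 3 mast cell and basophil, 1 and 5 eosinophil, 3 and 3 progenitor, 5 and 6 stromal and 2 and 2 epithelial genes were called lower. Cd48, Procr and Kdr were then not called. No call was made of Pax8 without control replicate 1 or control replicate 2 (adjusted p = 0.064 and 0.14, range 0.0043 to 0.14). Mcpt8 and Cxcl12 changed by -5.83 and -7.49 without VpR126, the latter in place of -6.87, Kdr by 2.99 without VpR99 and Procr by 3.51 without control replicate 1. The eosinophil median was -1.22 without control replicate 1 (camera adjusted p = 0.047, range 0.0028 to 0.53). Without VpR2020, 1 eosinophil gene was called, and without a low-count filter 4, and without VpR126 the epithelial list was not called (camera adjusted p = 0.061, range 0.0012 to 0.52).

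**Figure D2:**
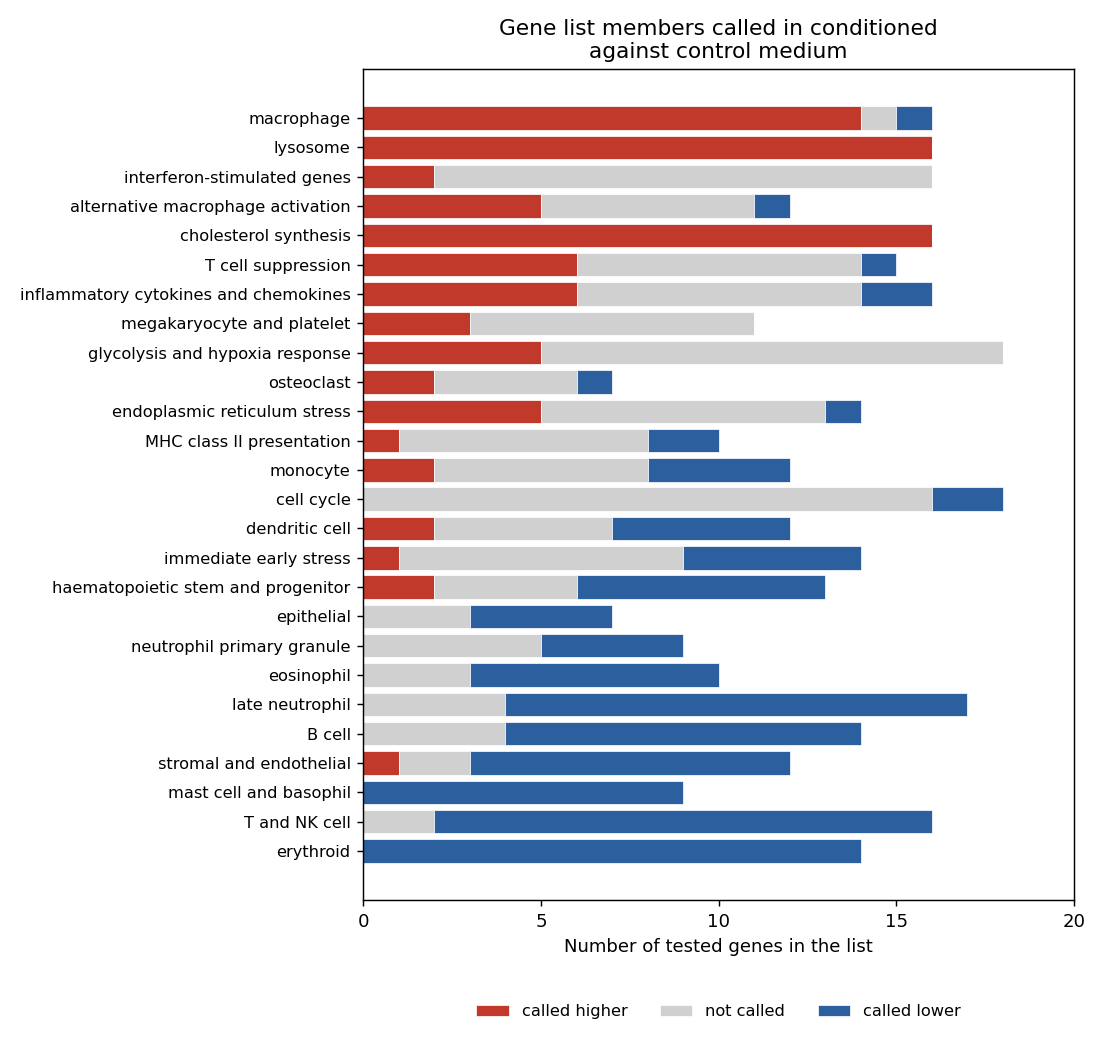
Number of tested genes (horizontal axis) of each of the 26 lists that were called higher (red), lower (blue) or not called (grey) in conditioned against control medium. All 16 lysosome and 16 cholesterol synthesis genes are red, and all 14 erythroid and 9 mast cell and basophil genes are blue.

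Monocyte, dendritic cell and osteoclast markers had no common direction. Of 12 monocyte genes 2 (Csf1r and Ms4a6c) rose and 4 (Ace, Nr4a1, Klf4 and Spn) fell (3 higher and 4 lower adjusted over the list alone, median -0.75, camera adjusted p = 0.48). Ace, a peptidase gene, fell by 6.14 ± 0.57. The transcription factor genes Nr4a1 and Klf4 changed by -4.12 and -2.21, but without control replicate 1 neither was called (-1.76 and -1.23, adjusted p = 0.075, range 5.4e-07 to 0.075, and 0.11, range 5.6e-05 to 0.11). Nr4a1 changed by -4.96 without control replicate 2, and Ace by -6.76 without VpR126. Ly6c2, the gene of the monocyte antigen Ly6C, had 733 ± 18.4 and 265 ± 187 CPM (adjusted p = 0.086), and was called lower without VpR99 or by DESeq2 (adjusted p = 0.015 and 0.028, range 0.015 to 0.24). Of 12 dendritic cell genes 5 (Zbtb46, Siglech, Flt3, Ccr9 and Cd209a) fell and 2 (Tcf4 and Bst2) rose (3 higher and 5 lower adjusted over the list alone, median -1.67, camera adjusted p = 0.24), with Siglech, a receptor gene of plasmacytoid dendritic cells, down from 53 ± 3.1 to 1.9 ± 1.55 CPM. Itgax, the CD11c gene, had 18.2 ± 0.428 and 49.3 ± 28.5 CPM (adjusted p = 0.10), and was called higher without VpR83 or by DESeq2 (adjusted p = 0.020 and 0.031, range 0.020 to 0.30). Of 7 osteoclast genes 2 (Atp6v0d2 and Dcstamp) rose and 1 (Car2) fell, the same counts adjusted over the list alone, and camera's direction was down (adjusted p = 0.96) while the median and mean were 0.26 and 0.48. Without control replicate 1 or 2, 1 and 3 monocyte genes and 3 and 3 dendritic cell genes were called lower and 0 of either list higher. The threshold was missed in the case of Atp6v0d2 without control replicate 1 (adjusted p = 0.052, range 7.1e-18 to 0.052) and of Dcstamp without control replicate 1, control replicate 2 or VpR99 (adjusted p = 0.18, 0.15 and 0.052, range 0.00019 to 0.18) or by voom or without a low-count filter (0.086 and 0.062). Under upper-quartile scaling or with library totals only, 0 dendritic cell genes were called higher, and by DESeq2 4 dendritic cell and 4 monocyte genes. Without VpR2020, 1 dendritic cell gene was called higher, and without VpR126 3 osteoclast genes were called lower. Without VpR126 Siglech changed by -5.55 in place of -4.82. The osteoclast median turned to -0.42 without VpR126, -0.14 by voom, -0.15 under the stricter filter and -0.04 with members of 1 list only.

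Smaller or less even differences were found in the other programmes. The glycolysis and hypoxia list was called higher (median 0.86, camera adjusted p = 0.019, and adjusted p = 0.69 with an estimated correlation), with 5 of 18 genes called (Pfkl, Hk2, Vegfa, Bnip3 and Pgam1) and 4 adjusted over the list alone. Pfkl, a phosphofructokinase gene, rose by 1.40 ± 0.27, and 0 of the genes were called without either control but 10 without VpR126 and 3 without VpR83, 3 under upper-quartile scaling or with library totals only, and 9 by DESeq2. The cell cycle list was called lower (median -1.06, camera adjusted p = 0.0066, and adjusted p = 0.69 with an estimated correlation), but only Birc5 and Cdc20 of its 18 genes were called and 0 adjusted over the list alone. Without VpR99, 10 cell cycle genes were called, without VpR126 4 and without VpR83, VpR2020 or either control 0. The count was 9 under upper-quartile scaling, 6 with library totals only, 7 by DESeq2, 4 by voom, 4 under the stricter filter and 0 without a filter. Of 10 MHC class II genes Ctss, a protease gene, rose by 2.91, and H2-Oa and H2-Ob, which encode a regulator of class II loading, fell (log2 fold changes of -2.20 and -2.69, 1 higher and 2 lower adjusted over the list alone, median -0.29, camera adjusted p = 0.63). H2-Ab1, a class II β chain gene, had 253 ± 16.4 and 159 ± 90.9 CPM (adjusted p = 0.26), and was called lower without VpR126 (adjusted p = 0.0055, range 0.0055 to 0.52), where 6 class II genes were called lower. The test no longer passed in the case of H2-Oa without control replicate 1 or control replicate 2 (adjusted p = 0.051 and 0.057, range 3.8e-06 to 0.057) and of H2-Ob without control replicate 1 or control replicate 2 (adjusted p = 0.058 and 0.059, range 1.5e-05 to 0.059). Of 14 endoplasmic reticulum stress genes 5 (Xbp1, Hspa5, Hsp90b1, Sesn2 and Calr) rose and Herpud1 fell (6 higher and 1 lower adjusted over the list alone, median 0.57, camera adjusted p = 0.37), with 1 and 0 higher without control replicate 1 or 2 and 3 without VpR83 or VpR2020 or under upper-quartile scaling. Herpud1 was called in none of the fits without control replicate 1, VpR83, VpR99 or VpR2020. With library totals only 1 stress gene was called higher, while Xbp1, Hsp90b1 and Sesn2 lost their calls (adjusted p = 0.062, 0.062 and 0.14). Of 14 immediate early genes 5 (Dusp1, Jund, Fosb, Ier2 and Hspa1a) fell and Ier3 rose (1 higher and 5 lower adjusted over the list alone, median -1.06, camera adjusted p = 0.13). Fosb had 227 and 11.6 CPM in the controls. Fosb, Dusp1 and Jund changed by -2.55, -1.36 and -1.03 in place of -5.93, -2.67 and -2.11 when control replicate 1 was left out. With control replicate 2 left out they changed by -6.84, -3.33 and -2.70, and Fosb changed by -7.13 without VpR83. Significance was lost in the case of Fosb without control replicate 1 (adjusted p = 0.16, range 0.00012 to 0.16) or without a low-count filter (0.074) and of Dusp1 without control replicate 1 (adjusted p = 0.064, range 6.8e-06 to 0.064). No call was made of Ier3 without control replicate 2 (adjusted p = 0.088, range 0.00011 to 0.088). Without control replicate 1, 1 immediate early gene was called lower and 2 were called higher, while without replicate 2 the list was called lower (camera adjusted p = 0.0057, range 0.0057 to 0.70).

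The conditioned libraries differed among themselves most in megakaryocyte and interferon-stimulated genes. The interferon list was called higher (median 2.78, camera adjusted p = 0.035, and adjusted p = 0.70 with an estimated correlation), but only Oas1a and Bst2 of its 16 genes were called and 0 adjusted over the list alone. DESeq2 called 11 interferon genes higher, voom as well as edgeR under upper-quartile scaling, with library totals only or under the stricter filter 1, and edgeR without a low-count filter 0. The list's mean over control was 0.01 log2 units with VpR83, 0.94 with VpR2020, 2.82 with VpR99 and 4.35 with VpR126, while the 2 controls differed by 0.26. The antiviral gene Ifit1 had 8.86 CPM under VpR83 and 272 under VpR126 medium. Without VpR83, 9 interferon genes were called, without VpR126 3 and without VpR99 or either control 0, and the list was not called without control replicate 1, VpR99 or VpR126 (camera adjusted p = 0.079, 0.084 and 0.069, range 0.0016 to 0.70), with a median of 1.82 without VpR126. Of 11 megakaryocyte and platelet genes 3 rose, also adjusted over the list alone (median 1.31, camera adjusted p = 0.47), namely the platelet chemokine genes Pf4 (6.73 ± 0.67) and Ppbp (5.46 ± 1.22) and the von Willebrand factor gene Vwf (3.56 ± 0.66). Itga2b, the platelet integrin αIIb gene, had 154 CPM under VpR126 medium, 2.6 to 7.63 CPM under the other 3, and 36.2 and 37.6 CPM in the controls. Without VpR126, 5 megakaryocyte genes were called lower beside 3 higher. The list's median was carried by that library. It turned to -2.06 without VpR126 (camera adjusted p = 0.50, range 0.17 to 0.82) and to -1.01 by voom. Over control, the median member lay at 3.20 log2 units in VpR126 and at -2.62, -1.65 and -1.39 in VpR83, VpR99 and VpR2020. The threshold was missed in the case of Ppbp without control replicate 1 or control replicate 2 (adjusted p = 0.11 and 0.088, range 8.0e-10 to 0.11) or by voom or without a low-count filter (0.052 and 0.071) and of Vwf without control replicate 1 or control replicate 2 (adjusted p = 0.070 and 0.066, range 4.7e-09 to 0.070). Ifit1 and Itga2b were chosen after their values were seen. With 1 library per line, differences between lines were not tested.

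**Figure D3:**
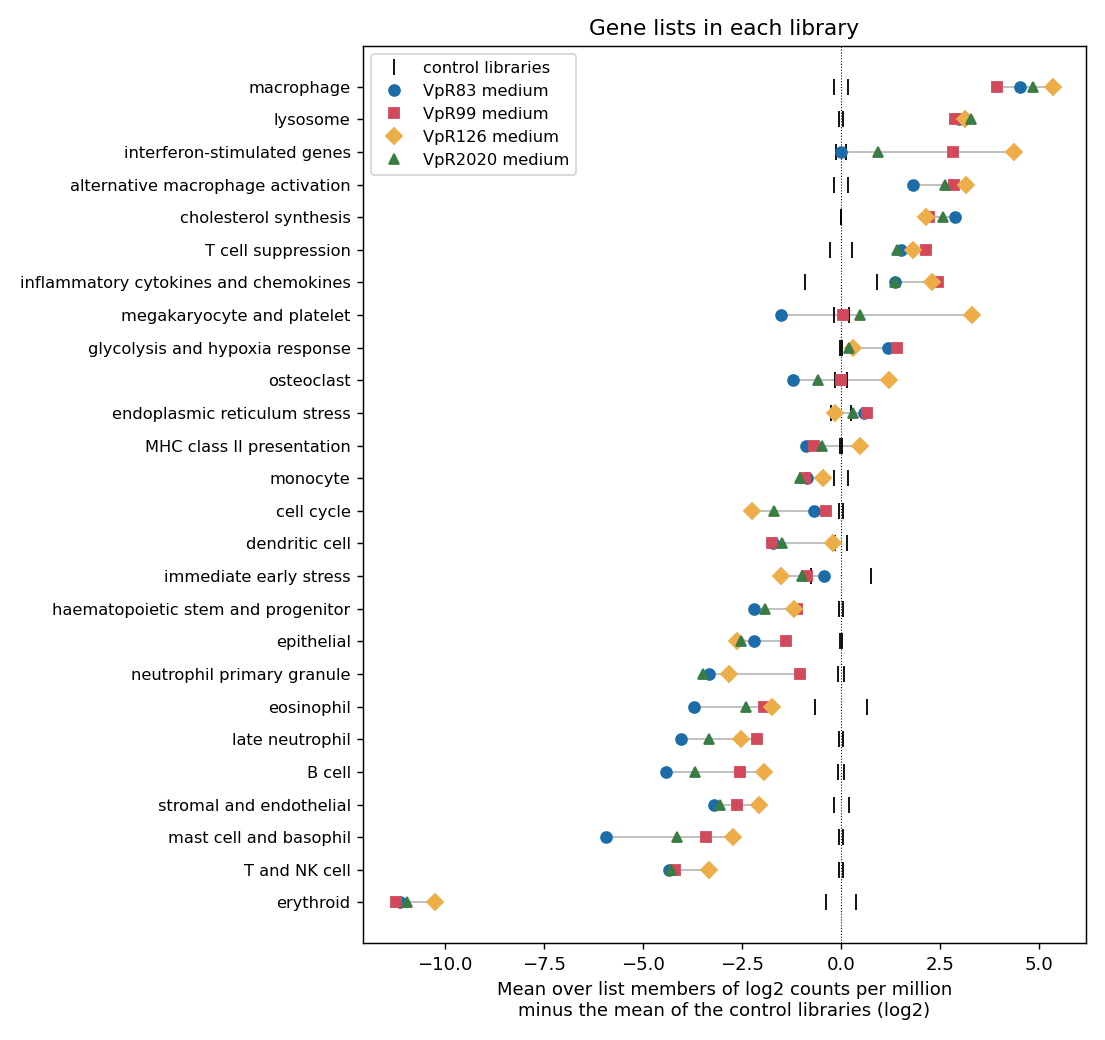
Mean over the members of each of the 26 lists of log2 CPM minus the mean of the control libraries (horizontal axis, log2 units), with 1 symbol per conditioned library and ticks for the 2 control libraries. The lysosome list lies between 2.87 and 3.27, and the interferon list between 0.01 and 4.35.

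In all, camera called 6 lists higher and 11 lower, and with an estimated correlation 0 and 0. By fry, the T cell suppression, macrophage and lysosome lists moved on balance up (adjusted p = 0.021, 0.00050 and 0.00031) and the erythroid list down (1.5e-05). The cholesterol and alternative activation lists also moved up (fry adjusted p = 0.0028 and 0.0043). Of the lists that camera called lower, all but the cell cycle list moved down by fry (adjusted p = 1.5e-05 to 0.047). Of the lists that camera called, fry did not call the interferon, glycolysis and cell cycle lists (adjusted p = 0.27, 0.14 and 0.17). Under the stricter filter the T and NK cell, stromal, alternative activation, interferon and glycolysis lists were not called (camera adjusted p = 0.26, 0.22, 0.054, 0.074 and 0.054), with medians of -1.73 and -1.47 in the first 2. That filter left 4 of 16 T and NK cell, 1 of 14 erythroid, 4 of 12 stromal and 2 of 7 epithelial genes to test, of which 2, 1, 3 and 1 were called lower. Of the other lists it left 11 of 12 alternative activation and all interferon and glycolysis genes. The stem and progenitor list was not called under upper-quartile scaling or with library totals only (0.073 and 0.078), nor the epithelial list with library totals only (0.053). With only the members that stand in 1 list, the stem and progenitor, alternative activation and interferon lists were not called (camera adjusted p = 0.22, 0.23 and 0.064), and the median of the stem and progenitor list was -0.86. By voom the alternative activation list was not called (camera adjusted p = 0.058).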

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

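The tests of carried-over or mixed control RNA and of depth behind the interferon list were chosen only after the results were seen. Among the 4 conditioned libraries, 8 of 68 values had 1 library far from the rest (Dixon ratio above 0.829). In 4 of them the other libraries were tied at 0 counts, which makes the ratio 1 by construction. Among the 58 values without such ties 4 had a library this far out, where chance gives about 5%. The ratio was 0.9011 for Pmp22, with VpR83 high, and 0.8545 for Ly6g, with VpR83 low. It was 1 for Hbb-bs and for Hba-a2, each with 1 count in VpR126 alone, and 1 for Cldn13 and Btnl10, each with 1 count in VpR99 alone. For the mean of the dendritic cell list it was 0.8318 and for that of the T and NK cell list 0.8559, with VpR126 high in both.

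The interferon-stimulated genes differed among the conditioned libraries by up to 4.34 log2 units in their mean. Greater depth of VpR99 was argued against as the source of this range, since its ends lay in VpR83 and VpR126. The other 3 libraries, with 19412158 to 28055913 counts, therefore differed by the same 4.343 log2 units. Whether depth bears on the value of VpR99 itself is not shown by these values. Control marrow RNA mixed into the conditioned libraries was argued against too, because the Hbb-bs counts allow at most 0.03605% of control RNA in any conditioned library, while the list in VpR83 lay at the control level. A candidate explanation that stays open is that the media of the 4 lines differ in interferon or in nucleic acids that induce it. With 1 library per line this was not tested, and neither was a difference in handling between libraries. The unexplained header tags are Ctrl for VpR83, which lay at the control level, T1 for VpR99 and LT2 for VpR126. Whatever these tags stand for may differ between the libraries together with the line, and was not tested.

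Granulocyte and B cell transcripts stayed in the conditioned libraries at different levels, with 0.993% to 6.75% of the control level of Ly6g and 8.41% to 24.3% of that of Ighm. Carry-over of control marrow RNA was argued against, since the percent left of Ly6g was at least 119.1 times that of Hbb-bs, taken at its floor or above, in every conditioned library. Surviving or newly formed cells of these types may differ between the media, which was not tested.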

How the results depend on the processing

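The thinning of VpR99 was the only alternative chosen after the data were seen. No called named gene and no called list reversed under the alternatives run. Of the other called genes, none that was also called in an alternative turned sign there, and the rest were not checked. The analysis as reported gave 3410 genes higher in conditioned medium and 2983 genes lower in conditioned medium, and 6 lists higher and 11 lower. With 1 library left out, genes higher ranged from 1283 to 3657 and genes lower from 918 to 3374, the lowest without control replicate 1 and the highest without VpR126. A lone control was assumed to vary like the conditioned libraries. At an adjusted p below 0.01 they were 1832 and 1280. The stricter filter left 3 lists higher and 7 lower, since by construction it removes genes high only in the 2 controls, while for the lists that were higher the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower at an adjusted p below 0.05, the lowest being 0.34. DESeq2 called 3938 and 3465 genes, without a list test, and voom 3112 and 3218. Of 117 called named genes, 67 kept their call wherever they were tested. Calls were lost for 46 without control replicate 1, 39 without replicate 2, 19 without a filter, 8 by voom and 0 after thinning VpR99. Folds moved by over 1.5 times for 22 of the called named genes without control replicate 1, 15 without replicate 2, 23 without VpR99, 15 without VpR126, 12 after thinning VpR99, 17 by voom and 6 by DESeq2. No paired analysis was possible because only the controls carry replicate numbers. Depth limits genes near the floor of 0.161 CPM in control replicate 2.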

Other observations

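The genes described first, apart from Siglech, and the thinning of VpR99 were chosen after the data were seen, and the alternatives were not run on these genes. Of 29 genes looked up, Siglech included, 17 were called higher, 4 lower and 8 were not called (edgeR, n = 2 and n = 4 libraries), and no theme was tested. Siglech, called lower, was fixed beforehand as a dendritic cell list gene, and the alternatives were run on it. Spp1, the osteopontin gene, rose from 13 ± 6.74 to 4977 ± 4828 CPM (8.57 ± 1.48, adjusted p = 0.0060). The fatty acid binding protein gene Fabp5 rose by 5.14 ± 0.26, the cholesterol exporter gene Abca1 by 5.03 ± 0.85, the scavenger receptor gene Cd36 by 4.48 ± 0.77 and the lipoprotein lipase gene Lpl by 4.17 ± 0.93. Fabp4, of the same family as Fabp5, rose by 2.78 ± 0.53. The exporter gene Abcg1 was not called (0.61 ± 0.39, adjusted p = 0.24) and neither were the nuclear receptor genes Nr1h3 (1.38 ± 0.75, adjusted p = 0.18) and Pparg (0.88 ± 0.36, adjusted p = 0.090). The macrophage transcription factor gene Maf rose by 6.17 ± 0.44 and the lipopolysaccharide receptor gene Tlr4 by 3.53 ± 0.17. Timd4, a phosphatidylserine receptor gene of resident macrophages, fell by 5.03 ± 1.10 from 2.28 ± 0.168 to 0.08 ± 0.144 CPM. The folate receptor gene Folr2 rose by 5.31 ± 1.27, and the hyaluronan receptor gene Lyve1 was not called (-2.33 ± 0.82, adjusted p = 0.061). The granulocyte transcription factor gene Cebpe fell by 2.81 ± 0.47, whereas Spi1, the PU.1 gene of myeloid cells, was not called (0.14 ± 0.19, adjusted p = 0.58).

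The many genes called between the media did not rest on the greater depth of VpR99, since 6429 were called after thinning it and 6393 before. Tumour cells carried over with the medium stay open as a source of some higher genes. The highest level of Krt8, Krt18 and Epcam in any conditioned library was 0.499 CPM of the library total, but no tumour cell library was analysed here, so whether the lines express these markers, as the bound set beforehand assumed, is not known. A lower number of lymphoid and erythroid cells may underlie the lower markers, and 71.43% of the tested B cell genes and 100% of the erythroid genes were called lower. The bound set beforehand in favour of that explanation asked for 80% in both lists, which the B cell share did not reach. The B cell share lay above the 50% set as against it. These shares cannot decide the question, since lower expression per cell would lower the same markers. Cells were not counted, so for the lists together fewer cells cannot be told apart from lower expression per cell. Likewise, for the higher genes, the macrophage, lysosome and cholesterol lists among them, higher expression per cell cannot be told apart from a changed mix of cells. Culture time stays open as well for both directions.

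The 2 control libraries differed in stress and cytokine genes, among others. Fosb had 227 and 11.6 CPM in replicates 1 and 2, Nr4a1 498 and 53.9, and Il6 16.8 and 1.36. The means of the inflammatory and immediate early lists differed between them by 1.83 and 1.51 log2 units, those of the eosinophil and erythroid lists by 1.30 and 0.76, and that of the lysosome list by 0.09.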
